A study of Streptococcus sanguinis SK36 with 12 samples.

How the data were processed

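RNA was measured by sequencing in 12 libraries of Streptococcus sanguinis SK36, 3 from each of 4 groups: untreated cells and cells held at 43 °C for 10, 20 or 30 min. Per the labels' protocols, cells were broken with beads, RNA was cleaned and treated with DNase on columns, ribosomal RNA was depleted with a bacterial kit and libraries were made with a kit that keeps the strand. The design text calls the replicates biological and independently grown, so they are treated as separate cultures. The authors deposited 1 table for the series with raw counts per gene and library, per the file headers, next to p-values and q-values of their 6 pairwise comparisons, whose test is not given in the sources used here. The aligner, the counter, the genome build, any read filter and whether counting used strand are not given in the sources used here. Overlapping and antisense genes can therefore share counts, and 0 of the 112 genes named here overlap another annotated entry by over 50 bp.

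The table lists 2432 features: 2271 genes, of which 862 have a symbol, 12 rRNAs, 61 tRNAs and 88 predicted RNAs. Genes are named by symbol, or by locus tag where the table gives none, and coordinates are the table's own, on a chromosome whose highest listed position is 2388435. The reference table of gene names matched 0 of the locus tags and was not used. Features annotated as rRNA or tRNA by their product and predicted RNAs stayed out of gene library sizes and tests. A further 20 value columns, of normalized counts and of group values, were not used. Total counts ranged from 2976512 to 7912291 per library, with median counts per gene from 464 to 1282. The 10 most abundant genes took 11.0% to 13.4% of gene counts. Chi-square per degree of freedom between libraries of a group ran from 2.12 to 97.0, so no pair lay within sampling noise and each library counted as 1 replicate.

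Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, its filterByExpr filter by group, and a robust quasi-likelihood fit to all 12 libraries with a term per group. This kept 2218 of 2271 genes, with a common biological coefficient of variation of 0.109 and 8 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each of 6 comparisons: each duration against untreated cells, and each pair of durations. The standard error is the absolute log2 fold change over the square root of F. Means ± SD are of TMM-scaled counts scaled to library size (CPM). Gene lists were fixed, by symbol and product words, before the data were examined, as were the tests, the main alternatives and the naming rule. They were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over 26 lists and 3 heat durations, and likewise over the 3 comparisons between durations). The named genes are, per duration, the 8 largest rises and 8 largest falls with a mean CPM of at least 20 and no overlap between the 6 libraries, all measured heat shock genes, and of each other list the 3 called members with the largest change where camera called it, otherwise 1. Between durations they are the 4 largest rises and 4 largest falls. Other members are named where few moved, after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

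The test was tried on simulated counts for 2218 genes with a seeded set changed by 1.5-fold, 2-fold or 4-fold. It recovered 73.1%, 98.5% and 98.5% of these at 10 min, 82.1%, 97.0% and 98.5% at 20 min and 83.6%, 97.0% and 98.5% at 30 min. False calls were 4.76%, 6.57% and 7% of all calls. Camera called 0 of 26 lists in unchanged data and, at each duration, only the ribosomal list once shifted by -0.5 (log2). Correlation within lists was not simulated. Similarity of durations was compared with 20 simulations of unchanged groups sharing the untreated libraries and with the overlap of independent lists. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library totals alone, no count filter, a CPM of at least 10 in 3 libraries, a replicate block, rRNA and tRNA kept, a 2-fold minimum, only the 2 groups compared, limma-voom with quality weights, fry or an estimated correlation for lists, and leaving out each library. Thinning each library to 2942835 gene counts, keeping predicted RNAs and taking 1 list member per run of adjacent genes on 1 strand were added after the data were seen. All unheated libraries belong to 1 group, so time in culture was not separated from heat.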

Results

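Gene expression was measured by RNA-seq in Streptococcus sanguinis SK36, an oral streptococcus that can also infect heart valves. Cultures grown without oxygen in brain-heart infusion at 37 °C were taken in late-log phase, either untreated or after 10, 20 or 30 min at 43 °C, with 3 separately grown cultures in each of the 4 groups. Total counts for replicates 1, 2 and 3 were 7093640, 5800944 and 6056160 in untreated cultures, 6467809, 6064595 and 7420289 at 10 min, 5439414, 5975846 and 7912291 at 20 min and 3371267, 2976512 and 3203343 at 30 min. rRNA took 0.662% ± 0.526 (SD, n = 3) of the counts in untreated libraries, 0.197% ± 0.112 at 10 min, 0.395% ± 0.225 at 20 min and 0.214% ± 0.0886 at 30 min. The series asks how expression changes with the length of the heat shock. No unheated culture was sampled at a later time, so each comparison with untreated cells covers the heat together with the added time in culture.

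Heat shock changed the expression of 1784 of 2218 tested genes at 1 or more of the 3 durations (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and 434 were called at none. Over all 3 durations, 410 were higher and 417 lower each time, while 43 changed in opposite directions at different durations. The first principal component of log2 CPM (counts scaled to library size) carried 68.5% of the variance, and the 4 groups did not overlap along it. Scaling mattered for direction, because library totals alone, in place of TMM factors, moved the median log2 fold change of all genes to 0.09 at 10 min, 0.24 at 20 min and 0.30 at 30 min. Changes are given relative to the TMM-scaled typical gene unless library totals are named. Values after gene names and list medians are log2 fold changes against untreated cultures, or between the durations compared, with 3 libraries per group. Camera, a test of a list against all other genes, called 10 of 26 lists at each duration, or 0 with an estimated correlation. With 1 member per run of adjacent genes on 1 strand, chosen after seeing the data, it called 4 each. Those were ribosomal proteins, aminoacyl-tRNA synthetases and transcription and translation factors throughout, with heat shock at 10 and 30 min and PTS sugar uptake at 20 min.

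After 10 min at 43 °C clpL and the GroE and DnaK chaperone genes were already high. clpL, a Clp ATPase chaperone gene (2099647 to 2101785, minus strand), went from 1106 ± 152 to 6677 ± 230.4 CPM (mean ± SD, n = 3), 6.04-fold (log2 2.59 ± 0.13 SE, edgeR adjusted p = 1.99e-07). groEL and groES, which encode the GroE chaperonin (218782 to 220709, plus strand), rose by 1.51 ± 0.06 and 1.42 ± 0.12, and the DnaK chaperone genes dnaK, dnaJ and grpE by 1.36 ± 0.09, 1.17 ± 0.08 and 1.26 ± 0.11. hrcA, the repressor gene of this regulon, rose by 0.83 ± 0.13 and the Clp ATPase gene clpE by 0.75 ± 0.08. In the heat shock list, 8 of 15 measured members rose, 2 fell and 5 did not pass (the same adjusted over the list alone). Their median was 0.75, 0.14 with 1 member per run (camera adjusted p = 1.38e-06, adjusted p = 0.0601 with an estimated correlation). The members that fell were htpX (-0.35), annotated as a heat shock protein, and clpX (-0.26), whose product feeds the ClpP protease. Values for members that did not pass were 0.28 for clpC, -0.01 for ctsR, -0.0035 for clpP, -0.16 for hslO and -0.09 for SSA_0009, and clpC was called by limma-voom (adjusted p = 0.0487).

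Beside clpL, the largest rises at 10 min were of SSA_0219 to SSA_0224, SSA_2023 and adh. The adjacent genes SSA_0219 to SSA_0224 (215507 to 218578, plus strand), annotated mainly as a mannose-type phosphotransferase system (PTS), rose together, with SSA_0220 going from 10.2 ± 2.42 to 80.1 ± 53.9 CPM, 7.92-fold (2.99 ± 0.60 SE, edgeR adjusted p = 0.00178). The other members were SSA_0219 (2.81), SSA_0221 (2.76), SSA_0222 (2.72) and SSA_0224 (2.87). SSA_2023, annotated as a fructan beta-fructosidase (2.61), and the alcohol dehydrogenase gene adh (2.50) also rose. Of the PTS sugar uptake list, 19 of 33 measured members rose, 0 fell and 14 did not pass (the same adjusted over the list alone). Their median was 0.76 (camera adjusted p = 0.00495, adjusted p = 0.673 with an estimated correlation). For glycolysis and fermentation, 14 of 24 measured members rose, 3 fell and 7 did not pass (14 rose and 5 fell adjusted over the list alone). Their median was 0.36, 0.18 with 1 member per run and no call (camera adjusted p = 0.00698, adjusted p = 0.328 with an estimated correlation), led by adhE (2.42), pdhC (2.01) and spxB (0.95), which encode an alcohol and acetaldehyde dehydrogenase, a subunit annotated as branched-chain alpha-keto acid dehydrogenase and pyruvate oxidase. Its members that fell were gpmA (-0.52), pykF (-0.30) and tpiA (-0.23), for phosphoglycerate mutase, pyruvate kinase and triosephosphate isomerase.

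**Figure D1:**
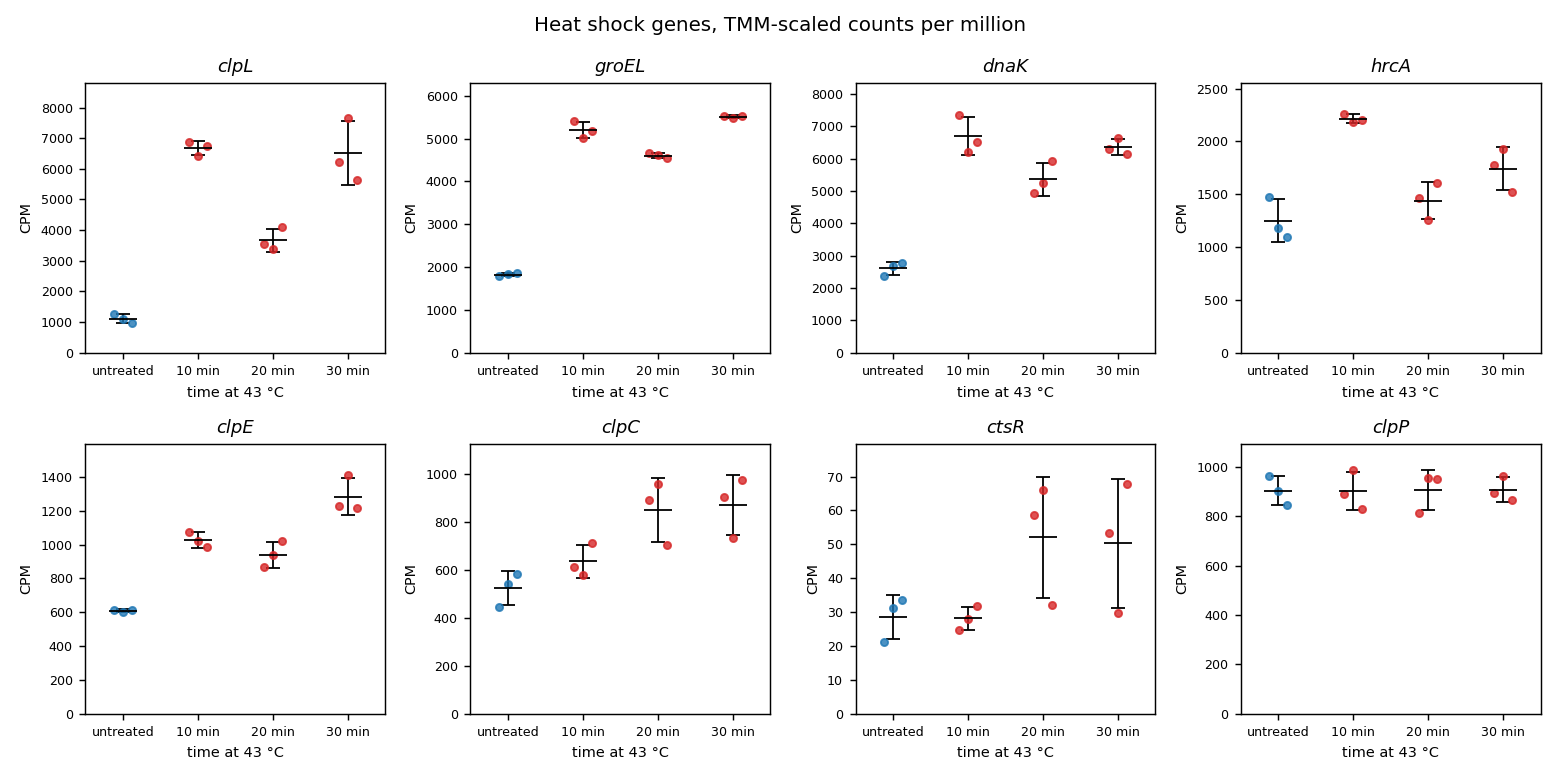
TMM-scaled CPM of 8 heat shock list genes in untreated cultures and after 10, 20 and 30 min at 43 °C, where points are libraries and bars the mean ± SD of 3. clpL rises from 1106 to 6677 CPM at 10 min, and clpP stays near 904 CPM.

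Translation lists were lower at 10 min. In the ribosomal protein list, 0 of 52 measured members rose, 48 fell and 4 did not pass (0 rose and 50 fell adjusted over the list alone). Their median was -0.64 (camera adjusted p = 2.06e-09, adjusted p = 0.217 with an estimated correlation), with rpsJ (-1.0), rplC (-0.96) and rplD (-0.93) falling most. Among aminoacyl-tRNA synthetases, 2 of 24 measured members rose, 15 fell and 7 did not pass (2 rose and 17 fell adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.00136, adjusted p = 0.372 with an estimated correlation), with serS (-1.06), SSA_0568 (-0.86) and pheS (-0.80) lowest and SSA_0889 (0.56) and hisS (0.16) higher. Transcription and translation factors moved the same way, as 0 of 24 measured members rose, 15 fell and 9 did not pass (0 rose and 17 fell adjusted over the list alone). Their median was -0.31 (camera adjusted p = 6.99e-04, adjusted p = 0.328 with an estimated correlation), with rpoA (-0.77), infA (-0.76) and infC (-0.73). For ribonucleotide reductase, which makes deoxynucleotides, 1 of 7 measured members rose and 6 fell (the same adjusted over the list alone). Their median was -0.86 (camera adjusted p = 0.00152, adjusted p = 0.217 with an estimated correlation), with nrdF (-0.93), nrdG (-0.93) and nrdD (-0.86), and the member that rose was nrdI (0.30), a flavoprotein gene. For amino acid synthesis, 4 of 63 measured members rose, 25 fell and 34 did not pass (3 rose and 23 fell adjusted over the list alone, 9 rose and 15 fell with library totals, median -0.10). Their median was -0.20, -0.11 with 1 member per run and no call (camera adjusted p = 0.0114, adjusted p = 0.673 with an estimated correlation), with the histidine genes hisD (-1.32), hisI (-1.31) and hisZ (-1.28) lowest, while argC (0.76), argJ (0.67), argB (0.72) and leuA (0.29) rose.

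The fatty acid list and the cobalamin, propanediol and ethanolamine list were called as lower at 10 min, calls lost without single libraries. For fatty acid synthesis, 0 of 12 measured members rose, 5 fell and 7 did not pass (the same adjusted over the list alone). Their median was -0.42, -0.28 with 1 member per run and no call (camera adjusted p = 0.0344, adjusted p = 0.673 with an estimated correlation), and camera no longer called it without untreated replicate 2 (0.0526) or 3 (0.0623) or 10 min replicate 2 (0.0806). The members that fell were SSA_1936 (-0.53), fabD (-0.51), fabK (-0.45), acpP (-1.06) and fabH (-0.82). The acpP call was lost without untreated replicate 1 (0.197) or 10 min replicate 1 (0.0771) or 3 (0.116), or with library totals (0.0509) or with only the 2 groups in the fit (0.115). Its value was -0.41 without untreated replicate 1. The SSA_1936 call was lost without untreated replicate 3 (0.0512), or with only the 2 groups in the fit (0.0507) (edgeR adjusted p). For cobalamin, propanediol and ethanolamine genes, 1 of 42 measured members rose, 15 fell and 26 did not pass (the same adjusted over the list alone). Their median was -0.20, 0.01 with 1 member per run and no call (camera adjusted p = 0.0177, adjusted p = 0.710 with an estimated correlation), with eutA (-1.11), eutQ (-1.11) and SSA_0520 (-1.10), while pduC (1.20) rose, and the list was not called without untreated replicate 3 (0.0724). These 2 lists had the lowest median loadings, percentiles 7.21 and 7.87 of all genes, on a component with 44.0% of the variance within groups, positive in 1 library of each group.

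The largest falls at 10 min outside these lists were SSA_1029 (-2.59), hlyIII (-2.09), SSA_1397 (-1.94), SSA_2149 (-1.59), rheA (-1.51), SSA_2148 (-1.45) and pacL (-1.31), where hlyIII is annotated as a hemolysin III-like protein, rheA as an RNA helicase and pacL as a cation-transporting ATPase. SSA_1029, of no annotated function (1046257 to 1047099, minus strand), went from 630.3 ± 87.8 to 105 ± 16.4 CPM, 6.03-fold lower. In all, 1102 genes changed at 10 min, 548 higher and 554 lower (edgeR), of which 118 rose and 56 fell by at least 2-fold. The split was 712 higher and 378 lower with library totals.

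The largest changes at 20 min were in sugar uptake genes. SSA_0219 to SSA_0224 were 116-fold to 137-fold above untreated, SSA_0220 reaching 1388 ± 347 CPM (7.10 ± 0.63 SE, edgeR adjusted p = 1.83e-06), with SSA_0221 (6.88), SSA_0222 (6.90) and SSA_0224 (6.97) close to it. SSA_2023 rose 110.5-fold to 1118 ± 272 CPM, adhE 24.0-fold to 8579 ± 713 CPM and adh 23.8-fold. In the PTS list, 28 of 33 measured members rose, 3 fell and 2 did not pass (29 rose and 3 fell adjusted over the list alone). Their median was 2.37, 1.43 with 1 member per run (camera adjusted p = 1.16e-06, adjusted p = 0.461 with an estimated correlation). The PTS members that fell were fruA (-1.35) for fructose, SSA_1752 (-4.34) for trehalose and ptsG (-0.61), annotated for glucose. SSA_1752 and the neighbouring dexS, a dextran glucosidase gene (1738200 to 1741965, minus strand), fell 20.3-fold and 10.8-fold, SSA_1752 from 10482 ± 23.2 to 518 ± 29.4 CPM. fruB, a 1-phosphofructokinase gene in the fruRBA run (1097678 to 1101311, plus strand), fell by 2.34 on the log2 scale, -2.96 without 20 min replicate 1.

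The glycolysis and fermentation, glycogen and arginine deiminase lists were called as higher at 20 min. For glycolysis and fermentation, 14 of 24 measured members rose, 7 fell and 3 did not pass (the same adjusted over the list alone). Their median was 1.11, -0.05 with 1 member per run and no call (camera adjusted p = 1.25e-04, adjusted p = 0.217 with an estimated correlation), with the pyruvate dehydrogenase genes pdhA (4.13) and pdhB (3.85) beside adhE (4.59). In the glycogen and amylase list, 10 of 14 measured members rose, 3 fell and 1 did not pass (the same adjusted over the list alone). Their median was 1.02 (camera adjusted p = 0.00281, adjusted p = 0.328 with an estimated correlation), with glgB (2.77), glgC (2.75) and glgD (2.78) highest and amy (-0.21), malP (-1.53) and malQ (-1.63) lower. In the arginine deiminase system list, 5 of 5 measured members rose and 0 fell (the same adjusted over the list alone). Their median was 0.59 (camera adjusted p = 0.0173, adjusted p = 0.316 with an estimated correlation), with arcT (1.71), arcC (1.62) and sagP (0.59) the largest, where sagP encodes arginine deiminase. That list also holds argR (0.21), a repressor of arginine synthesis, and queA (0.23), a tRNA modification gene.

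The GroE and DnaK chaperone genes and clpL were above untreated at 20 min too. clpL was 3.32-fold above untreated (1.73 ± 0.13 SE), and groES (1.41), groEL (1.34), dnaJ (1.07), dnaK (1.04) and grpE (0.90) rose. In the heat shock list, 9 of 15 measured members rose, 2 fell and 4 did not pass (the same adjusted over the list alone). Their median was 0.70, 0.34 with 1 member per run and no call (camera adjusted p = 0.00855, adjusted p = 0.209 with an estimated correlation). clpE (0.63), clpC (0.70) and ctsR (0.87), the repressor gene of the Clp genes, rose as well, but the ctsR call was lost without untreated replicate 1 (0.0983) or 20 min replicate 1 (0.0724) or 2 (0.101). htpX (-0.35) and SSA_0009 (-0.25) fell, the latter not called without 20 min replicate 2 (0.0684) or 3 (0.0534), and neither fell with library totals (edgeR adjusted p = 0.0990 and 0.825). hrcA (0.20), clpX (-0.12), clpP (0.0023) and hslO (0.05) did not pass, and with library totals hrcA, clpP and hslO did, as higher. Without untreated replicate 1 hrcA stood at 0.34 and was called. The SSA_0009 call was also lost after thinning (0.0548). In that list against 10 min, 3 of 15 measured members rose, 5 fell and 7 did not pass (the same adjusted over the list alone, 4 rose and 2 fell with library totals, median 0.03). Their median was -0.10 (camera adjusted p = 0.413).

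**Figure D2:**
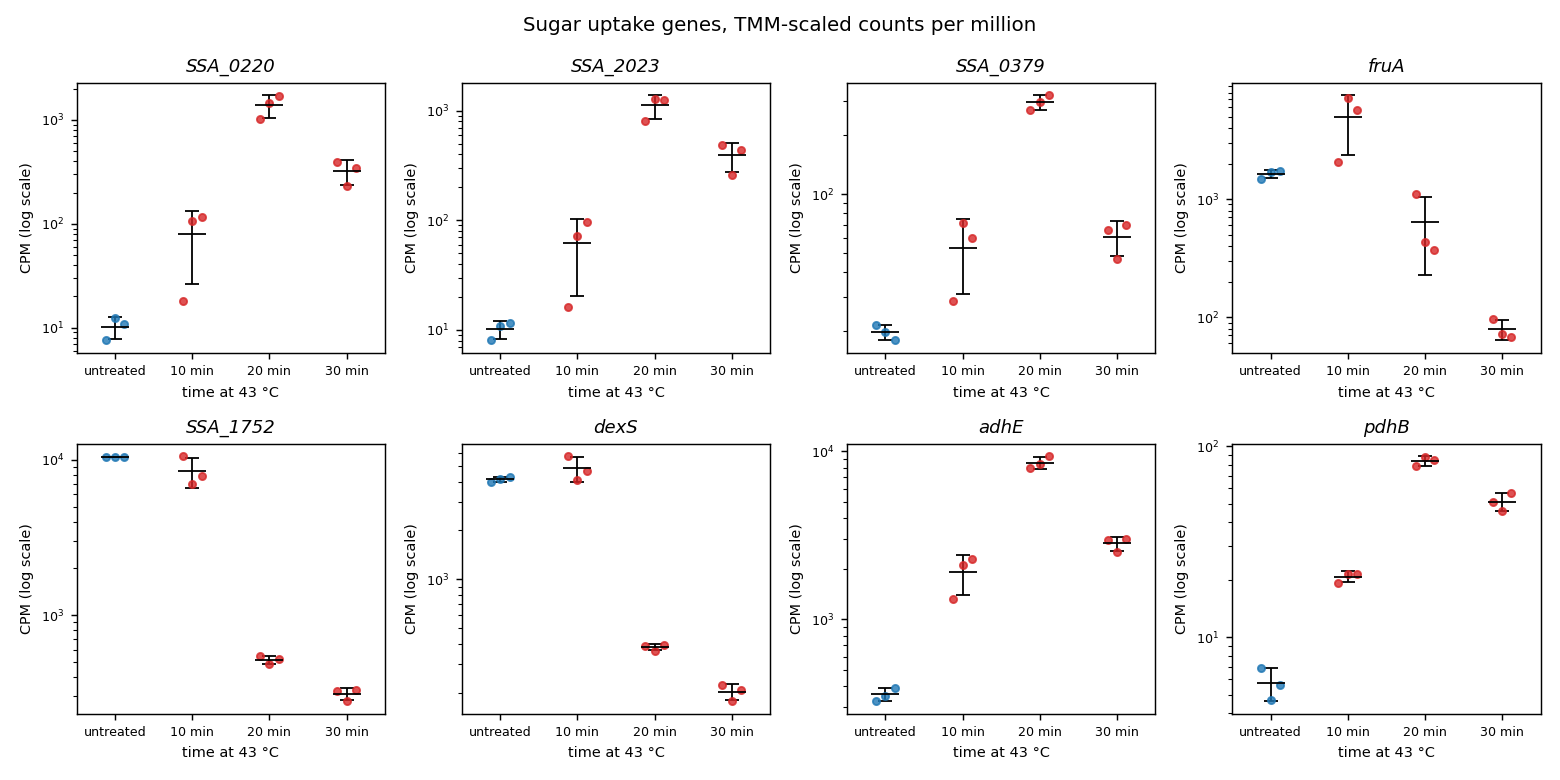
TMM-scaled CPM on log axes of 8 sugar uptake and fermentation genes by time at 43 °C, where points are libraries and bars the mean ± SD of 3. SSA_0220 peaks at 1388 CPM at 20 min, and fruA rises at 10 min and drops to 79.1 CPM at 30 min.

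Ribosomal protein genes fell at 20 min, 51 of them with library totals. In that list, 0 of 52 measured members rose and 52 fell (the same adjusted over the list alone). Their median was -1.27 (camera adjusted p = 3.04e-18, adjusted p = 0.107 with an estimated correlation), with rpsJ (-1.80), rplC (-1.68) and rpmB (-1.67) lowest. rpsJ, for ribosomal protein S10 (107912 to 108220, plus strand), went from 1688 ± 228 to 486 ± 21.1 CPM. For transcription and translation factors, 0 of 24 measured members rose, 21 fell and 3 did not pass (the same adjusted over the list alone). Their median was -0.65 (camera adjusted p = 2.39e-06, adjusted p = 0.217 with an estimated correlation), with infC (-1.57), rpoA (-1.48) and typA (-1.45). For aminoacyl-tRNA synthetases, 1 of 24 measured members rose, 18 fell and 5 did not pass (1 rose and 19 fell adjusted over the list alone, 5 rose and 10 fell with library totals, median -0.06). Their median was -0.29 (camera adjusted p = 0.0160, adjusted p = 0.628 with an estimated correlation), with serS (-0.87) and metS (-0.75) lower and SSA_0889 (0.73), a short isoleucyl-tRNA synthetase entry of 192 bp, higher. In the ribonucleotide reductase list, 1 of 7 measured members rose, 5 fell and 1 did not pass (the same adjusted over the list alone). Their median was -1.13, -0.60 with 1 member per run and no call (camera adjusted p = 0.00589, adjusted p = 0.231 with an estimated correlation), with nrdD (-1.29), nrdF (-1.25) and nrdG (-1.17) falling and nrdI (0.27) rising. For fatty acid synthesis, 1 of 12 measured members rose and 11 fell (the same adjusted over the list alone, 1 rose and 6 fell with library totals, median -0.44). Their median was -0.67, -0.13 with 1 member per run and no call (camera adjusted p = 0.0141, adjusted p = 0.673 with an estimated correlation), with acpP (-2.06), fabH (-1.70) and fabK (-0.95), acpP at -1.41 without untreated replicate 1, and SSA_1650 (0.28) higher.

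Further large falls at 20 min were SSA_1029 (-2.95), rheA (-2.12), SSA_0705 (-1.91) and ccl (-1.89). In all, 1453 genes changed, 737 higher and 716 lower (edgeR), of which 256 rose and 151 fell by at least 2-fold. The split was 1100 higher and 413 lower with library totals.

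At 30 min fructose and trehalose genes were far below untreated while the mannose-type genes stayed above it. fruB, fruA and fruR, for 1-phosphofructokinase, the fructose PTS and its repressor, were 25.1-fold, 20.6-fold and 14.9-fold lower (-4.65 ± 0.59, -4.36 ± 0.52 and -3.90 ± 0.48 SE, edgeR), fruA at 79.1 ± 15.5 CPM against 1630.1 ± 132 in untreated cultures. SSA_1752 and dexS were 33.6-fold and 20.3-fold lower. SSA_0224 (5.56), SSA_0222 (5.32), SSA_2023 (5.29), SSA_0221 (5.14), SSA_0220 (5.00) and SSA_0219 (4.63) remained the largest rises, followed by adh (3.49) and pdhA (3.39). Of the PTS list, 27 of 33 measured members rose, 3 fell and 3 did not pass (28 rose and 3 fell adjusted over the list alone). Their median was 1.16 (camera adjusted p = 0.0504), so camera did not call it, although it did without 30 min replicate 2 (0.0285). For glycolysis and fermentation, 14 of 24 measured members rose, 6 fell and 4 did not pass (14 rose and 7 fell adjusted over the list alone). Their median was 0.71, 0.10 with 1 member per run and no call (camera adjusted p = 0.00166, adjusted p = 0.231 with an estimated correlation), with pdhB (3.14) and pdhC (3.21) next to pdhA.

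GroE, DnaK and clpL genes were high at 30 min, clpL at 6507 ± 1050 CPM, 5.89-fold above untreated (2.56 ± 0.13 SE, edgeR adjusted p = 3.97e-08). In the heat shock list, 10 of 15 measured members rose, 1 fell and 4 did not pass (the same adjusted over the list alone). Their median was 0.83, 0.41 with 1 member per run (camera adjusted p = 1.05e-04, adjusted p = 0.0816 with an estimated correlation), with groES (1.71), groEL (1.60), dnaK (1.29), dnaJ (1.20), grpE (1.13), clpE (1.08), clpC (0.73) and hrcA (0.48). ctsR (0.83) was called, but not without untreated replicate 1 (0.121) or 2 (0.0617) or 30 min replicate 1 (0.0863) or 3 (0.163). htpX fell (-0.24), a call lost without 30 min replicate 1 (0.0633) and, with library totals, reversed in sign. clpX (0.09), clpP (0.01), hslO (0.06) and SSA_0009 (-0.08) did not pass, and all of these were called as higher with library totals. In the oxidative stress list, 10 of 16 measured members rose, 3 fell and 3 did not pass (the same adjusted over the list alone). Their median was 0.74 (camera adjusted p = 0.0177, adjusted p = 0.665 with an estimated correlation), with tpx (1.60), nox (1.56) and SSA_1130 (1.29) highest, where tpx encodes a thiol peroxidase and nox an NADH oxidase that forms water. Its members dps (-0.75), nrdH (-0.64) and SSA_1865 (-0.91) fell.

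Ribosomal protein genes stayed low at 30 min, where 0 of 52 measured members rose and 52 fell (the same adjusted over the list alone). Their median was -1.25 (camera adjusted p = 2.25e-16, adjusted p = 0.115 with an estimated correlation), with rpsJ (-1.66), rplQ (-1.59) and rpmB (-1.56). For transcription and translation factors, 0 of 24 measured members rose, 21 fell and 3 did not pass (the same adjusted over the list alone). Their median was -0.64 (camera adjusted p = 7.93e-06, adjusted p = 0.231 with an estimated correlation), with infC (-1.68), rpoA (-1.42) and infA (-1.26). Among aminoacyl-tRNA synthetases, 1 of 24 measured members rose, 18 fell and 5 did not pass (the same adjusted over the list alone, 5 rose and 9 fell with library totals, median -0.05). Their median was -0.33 (camera adjusted p = 0.00969, adjusted p = 0.572 with an estimated correlation), with serS (-1.14) and pheS (-0.77) lower and SSA_0889 (1.09) higher. For ribonucleotide reductase, 1 of 7 measured members rose and 6 fell (the same adjusted over the list alone). Their median was -1.11, -0.72 with 1 member per run and no call (camera adjusted p = 0.00589, adjusted p = 0.231 with an estimated correlation), with nrdD (-1.25), nrdF (-1.20) and nrdG (-1.12) falling and nrdI (0.25) rising. For fatty acid synthesis, 0 of 12 measured members rose, 9 fell and 3 did not pass (0 rose and 10 fell adjusted over the list alone, 1 rose and 5 fell with library totals, median -0.26). Their median was -0.54, -0.14 with 1 member per run and no call (camera adjusted p = 0.0485, adjusted p = 0.673 with an estimated correlation), not called without untreated replicate 2 (0.0656) or 3 (0.0695) or 30 min replicate 2 (0.0778). Its members acpP (-1.81), fabH (-1.61) and fabK (-0.85) fell, acpP at -1.16 without untreated replicate 1.

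Genes of the pyrimidine list and the argininosuccinate genes argG and argH were lower at 30 min. In the pyrimidine list, 2 of 13 measured members rose, 7 fell and 4 did not pass (the same adjusted over the list alone). Their median was -0.62, -0.11 with 1 member per run and no call (camera adjusted p = 0.0136, adjusted p = 0.572 with an estimated correlation), with pyrR (-1.54), pyrP (-1.20) and pyrB (-1.10) lowest and pyrDA (0.19) and pyrC (0.71) higher. For amino acid synthesis, 6 of 63 measured members rose, 30 fell and 27 did not pass (5 rose and 30 fell adjusted over the list alone, 17 rose and 24 fell with library totals, median 0.07). Their median was -0.21 (camera adjusted p = 0.00640, adjusted p = 0.673 with an estimated correlation), with the arginine genes argH (-2.09), argG (-2.00) and argC (-1.37) lowest. argG, for argininosuccinate synthase (2142306 to 2143505, minus strand), went from 1103 ± 32.4 to 276 ± 13.7 CPM. The largest falls also took in SSA_1029 (-3.22), malQ (-2.30) and rheA (-2.17), malQ encoding a 4-alpha-glucanotransferase. In all, 1480 genes changed at 30 min, 742 higher and 738 lower (edgeR), of which 246 rose and 184 fell by at least 2-fold. The split was 1154 higher and 425 lower with library totals.

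Several lists were not called by camera at any duration, although single members moved. For purine synthesis, of 14 measured, 2 rose and 3 fell at 10 min, 3 and 5 at 20 min and 4 and 6 at 30 min (the same adjusted over the list alone, 2 and 2, 6 and 1, 6 and 3 with library totals, camera adjusted p = 0.418, 0.975 and 0.975), with purK at -0.70 at 10 min and purH at 0.89 and 0.94 at 20 and 30 min. At 30 min its median was 0.14, its mean 0.06 and camera's direction down. In other proteases and folding factors, of 27 measured, 6 rose and 6 fell at 10 min, 8 and 8 at 20 min and 11 and 5 at 30 min (4 and 5, 7 and 8, 11 and 5 adjusted over the list alone, 9 and 4, 16 and 3, 20 and 3 with library totals, camera adjusted p = 0.768, 0.975 and 0.465), the dipeptidase gene SSA_1591 rising by 1.28, 4.03 and 2.10. At 10 min its median was 0.01, its mean 0.06 and camera's direction down, at 20 min its median was -0.01, 0.22 with library totals, its mean 0.25 and camera's direction up. The F-type ATPase list was mixed, and of 14 measured, 0 rose and 4 fell at 10 min, 4 and 7 at 20 min and 6 and 0 at 30 min (0 and 4, 4 and 8, 5 and 0 adjusted over the list alone, 1 and 3, 6 and 4, 13 and 0 with library totals, camera adjusted p = 0.418, 0.418 and 0.322). Its F-type members uncE (-0.62 at 10 min) and uncB (-0.79 at 20 min) fell, and ntpA, of the V-type ATPase that the list also holds, rose at 30 min (0.59). For competence, of 11 measured, 0 rose and 1 fell at 10 min, 0 and 4 at 20 min and 0 and 4 at 30 min (0 and 0, 0 and 4, 0 and 4 adjusted over the list alone, camera adjusted p = 0.679, 0.312 and 0.452), with comC, the competence peptide gene, at -1.25 and -1.61 at 20 and 30 min. At 30 min its median was -0.27, 0.0026 with library totals. For DNA repair, of 29 measured, 4 rose and 6 fell at 10 min, 13 and 5 at 20 min and 15 and 4 at 30 min (3 and 4, 13 and 5, 16 and 4 adjusted over the list alone, 7 and 4, 23 and 1, 25 and 1 with library totals, camera adjusted p = 0.857, 0.322 and 0.116), with ung at 0.45, xseB at 0.81 and rexB at 0.70 at 10, 20 and 30 min. At 10 min its median was -0.02, 0.07 with library totals, its mean 0.01 and camera's direction down.

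Cell wall, division and surface genes also went uncalled as lists. For peptidoglycan synthesis, of 28 measured, 2 rose and 13 fell at 10 min, 5 and 14 at 20 min and 5 and 12 at 30 min (the same adjusted over the list alone, 3 and 6, 10 and 6, 13 and 5 with library totals, camera adjusted p = 0.322, 0.294 and 0.418), while glmS, which makes glucosamine-6-phosphate, rose by 1.46, 1.26 and 1.23. At 20 min its median was -0.16, 0.07 with library totals, at 30 min it was -0.13, 0.15 with library totals. For cell envelope stress and teichoic acids, of 11 measured, 0 rose and 2 fell at 10 min, 0 and 7 at 20 min and 1 and 6 at 30 min (0 and 0, 0 and 7, 1 and 6 adjusted over the list alone, 0 and 0, 1 and 0, 3 and 1 with library totals, camera adjusted p = 0.438, 0.30 and 0.415), with dltA at -0.18 at 10 min and licD1 at -0.48 and -0.70 at 20 and 30 min. At 30 min its median was -0.26, 0.02 with library totals. The dltA call was lost without untreated replicate 1 (0.0724) or 10 min replicate 2 (0.0635) or 3 (0.0636), or with library totals (0.184), after thinning all libraries to equal gene totals (0.0715) or with only the 2 groups in the fit (0.102), and the licD1 call at 20 min without untreated replicate 3 (0.0597) or 20 min replicate 2 (0.0527) or 3 (0.0645), or with library totals (0.197) (edgeR adjusted p). In cell division and chromosome replication, of 31 measured, 2 rose and 10 fell at 10 min, 3 and 12 at 20 min and 3 and 13 at 30 min (2 and 9, 2 and 11, 2 and 11 adjusted over the list alone, 5 and 6, 11 and 4, 15 and 4 with library totals, camera adjusted p = 0.116, 0.172 and 0.408), with ssb, for a single-stranded DNA-binding protein, at -0.72, -1.48 and -1.37. At 20 min its median was -0.08, 0.15 with library totals, at 30 min it was -0.15, 0.13 with library totals. Among type IV pili, of 6 measured, 1 rose and 0 fell at 10 min, 2 and 3 at 20 min and 0 and 3 at 30 min (the same adjusted over the list alone, 1 and 0, 2 and 1, 2 and 1 with library totals, camera adjusted p = 0.857, 0.818 and 0.408), where pulA (0.64 at 10 min) and SSA_0453 (2.43 at 20 min) are annotated as pullulanases and SSA_2317 (-1.57 at 30 min) as a pilus retraction ATPase. At 10 min its median was -0.09, 0.01 with library totals, its mean 0.05 and camera's direction up, at 20 min its median was -0.21, 0.02 with library totals, its mean 0.19 and camera's direction up, at 30 min its median was -0.14, 0.13 with library totals. For surface adhesins and sortases, of 19 measured, 8 rose and 1 fell at 10 min, 6 and 5 at 20 min and 8 and 5 at 30 min (8 and 1, 5 and 4, 8 and 6 adjusted over the list alone, 11 and 1, 11 and 1, 12 and 2 with library totals, camera adjusted p = 0.0861, 0.857 and 0.636), with SSA_1666 at 1.09 at 10 min and SSA_1112 at 1.65 and 2.74 at 20 and 30 min. That list was called at 10 min without 10 min replicate 2 (0.0372).

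For metal uptake, of 21 measured, 10 rose and 5 fell at 10 min, 13 and 6 at 20 min and 9 and 7 at 30 min (11 and 5, 13 and 6, 10 and 7 adjusted over the list alone, 12 and 5, 15 and 6, 14 and 5 with library totals, camera adjusted p = 0.418, 0.641 and 0.966), and the zinc permease gene adcB stood at -1.25, -1.76 and -1.52. At 20 min its median was 0.24, its mean -0.08 and camera's direction down. Of transposases and integrases, of 4 measured, 2 rose and 0 fell at 10 min, 3 and 0 at 20 min and 2 and 0 at 30 min (3 and 0, 3 and 0, 2 and 0 adjusted over the list alone, camera adjusted p = 0.418, 0.329 and 0.329), with the integrase gene SSA_2295 at 0.77, 1.18 and 2.09. Some lists called at 1 duration were not at others. In the oxidative stress list, of 16 measured, 6 rose and 3 fell at 10 min and 10 and 3 at 20 min (the same adjusted over the list alone, camera adjusted p = 0.452 and 0.0715), with nox at 0.88 and 2.63, the former 0.57 without 10 min replicate 2. Camera called it at 20 min without untreated replicate 1 (0.0458) or 20 min replicate 1 (0.0393). For pyrimidine synthesis, of 13 measured, 5 rose and 2 fell at 10 min and 2 and 7 at 20 min (the same adjusted over the list alone, 6 and 1, 4 and 3 with library totals, camera adjusted p = 0.857 and 0.329), with pyrH at -0.78 and -0.78. At 10 min its median was 0.05, its mean -0.02 and camera's direction up, at 20 min its median was -0.23, 0.00071 with library totals. For the arginine deiminase system, of 5 measured, 2 rose and 0 fell at 10 min and 5 and 0 at 30 min (the same adjusted over the list alone, 5 and 0, 5 and 0 with library totals, camera adjusted p = 0.295 and 0.0715), with arcT at 0.45 and 0.97. For amino acid synthesis, of 63 measured, 10 rose and 28 fell at 20 min (the same adjusted over the list alone, 22 and 12 with library totals, camera adjusted p = 0.0715), with argG at -1.60, and was called without untreated replicate 1 (0.0274) or 20 min replicate 1 (0.0393) or 2 (0.0495). At 20 min its median was -0.21, 0.02 with library totals. For glycogen and amylase, of 14 measured, 7 rose and 2 fell at 10 min and 6 and 6 at 30 min (7 and 2, 7 and 6 adjusted over the list alone, camera adjusted p = 0.321 and 0.857), with glgB at 0.75 and malQ at -2.30. At 30 min its median was 0.28, its mean 0.01 and camera's direction down. For cobalamin, propanediol and ethanolamine genes, of 42 measured, 10 rose and 2 fell at 20 min and 5 and 21 at 30 min (9 and 2, 5 and 20 adjusted over the list alone, 15 and 2, 8 and 9 with library totals, camera adjusted p = 0.418 and 0.117), with SSA_0509, a propanediol gene, at 1.75 and eutA at -1.36. That list was called at 30 min without untreated replicate 1 (0.0238) or 30 min replicate 1 (0.0377). Camera also called it at 30 min with library totals (0.0216), as it did DNA repair (0.0446) and the arginine deiminase system (0.0381) at 30 min and surface adhesins at 10 min (0.0446).

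**Figure D3:**
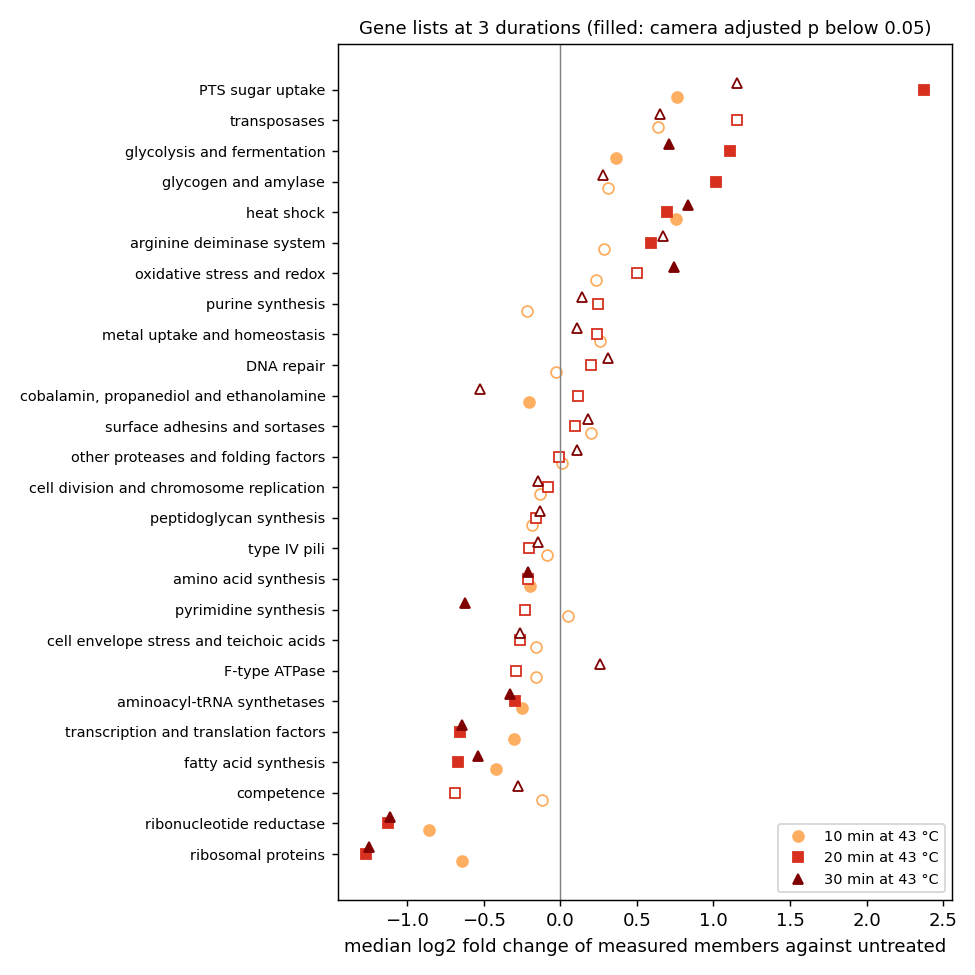
Median log2 fold change against untreated cultures of the measured members of 26 gene lists at 10, 20 and 30 min, filled where camera's adjusted p is under 0.05. PTS sugar uptake at 20 min is highest at 2.37, and ribosomal proteins at 20 min lowest at -1.27.

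Between 10 and 20 min the mannose-type PTS genes rose further while fructose and trehalose genes turned down. SSA_0222 was 18.1-fold higher at 20 than at 10 min (4.18 ± 0.56 SE, edgeR adjusted p = 1.40e-04), with SSA_2023 (4.17), SSA_0221 (4.12) and SSA_0220 (4.11). fruB (-4.17), SSA_1752 (-4.04), dexS (-3.66) and fruR (-3.17) fell most, fruB at -4.82 without 20 min replicate 1. In the PTS list, 24 of 33 measured members rose, 3 fell and 6 did not pass (the same adjusted over the list alone). Their median was 1.58, 0.55 with 1 member per run and no call (camera adjusted p = 5.67e-07, adjusted p = 0.458 with an estimated correlation). Of ribosomal proteins, 0 of 52 measured members rose, 45 fell and 7 did not pass (0 rose and 48 fell adjusted over the list alone, 1 rose and 33 fell with library totals, median -0.54). Their median was -0.67 (camera adjusted p = 2.45e-12, adjusted p = 0.315 with an estimated correlation). Among cobalamin, propanediol and ethanolamine genes, 22 of 42 measured members rose, 1 fell and 19 did not pass (23 rose and 1 fell adjusted over the list alone). Their median was 0.65, -0.14 with 1 member per run and no call (camera adjusted p = 6.64e-05, adjusted p = 0.662 with an estimated correlation). In glycogen and amylase, 10 of 14 measured members rose, 2 fell and 2 did not pass (10 rose and 3 fell adjusted over the list alone). Their median was 0.54 (camera adjusted p = 3.23e-04, adjusted p = 0.315 with an estimated correlation). For glycolysis and fermentation, 14 of 24 measured members rose, 8 fell and 2 did not pass (14 rose and 10 fell adjusted over the list alone). Their median was 0.69, -0.21 with 1 member per run and no call (camera adjusted p = 4.73e-04, adjusted p = 0.315 with an estimated correlation). Among transcription and translation factors, 0 of 24 measured members rose, 14 fell and 10 did not pass (0 rose and 15 fell adjusted over the list alone, 0 rose and 9 fell with library totals, median -0.12). Their median was -0.26 (camera adjusted p = 4.73e-04, adjusted p = 0.458 with an estimated correlation). In the arginine deiminase system, 3 of 5 measured members rose, 0 fell and 2 did not pass (the same adjusted over the list alone, 5 rose and 0 fell with library totals, median 0.31). Their median was 0.18 (camera adjusted p = 0.0207, adjusted p = 0.417 with an estimated correlation). In all, 983 genes differed, 513 higher and 470 lower at 20 min (edgeR), of which 144 rose and 27 fell by at least 2-fold. The split was 833 higher and 271 lower with library totals. Camera further called fatty acid synthesis without 10 min replicate 2 (0.04998), oxidative stress and redox without 10 min replicate 2 (0.0192) or 20 min replicate 1 (0.0290) and pyrimidine synthesis without 10 min replicate 2 (0.0398) or 20 min replicate 1 (0.0371), and with library totals DNA repair (0.0324) and oxidative stress and redox (0.0395).

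Between 20 and 30 min most 2-fold changes were falls. fruA was 8.08-fold lower at 30 than at 20 min (-3.01 ± 0.50 SE, edgeR adjusted p = 0.00154, log2 difference -2.35 without 20 min replicate 1), with SSA_0379 (-2.28) and fruR (-2.24), where SSA_0379 is a beta-glucoside PTS gene. fruB fell as well (-2.31), but was not called without 20 min replicate 1 (0.0662) or 30 min replicate 2 (0.0785) or 3 (0.0649). The largest rises were SSA_1112 (1.09), SSA_1052 (1.02), SSA_0288 (0.97) and lacC (0.94), of which SSA_1112 is annotated as a cell wall surface anchor protein and lacC as tagatose-6-phosphate kinase. Of glycogen and amylase genes, 0 of 14 measured members rose, 12 fell and 2 did not pass (the same adjusted over the list alone). Their median was -1.05 (camera adjusted p = 1.70e-18, still called at adjusted p = 0.0330 with an estimated correlation). In the PTS list, 0 of 33 measured members rose, 20 fell and 13 did not pass (1 rose and 24 fell adjusted over the list alone). Their median was -0.89 (camera adjusted p = 2.53e-14, adjusted p = 0.315 with an estimated correlation). For cobalamin, propanediol and ethanolamine, 1 of 42 measured members rose, 14 fell and 27 did not pass (1 rose and 22 fell adjusted over the list alone). Their median was -0.60, -0.30 with 1 member per run and no call (camera adjusted p = 3.43e-10, adjusted p = 0.458 with an estimated correlation). In the F-type ATPase list, 8 of 14 measured members rose, 0 fell and 6 did not pass (the same adjusted over the list alone). Their median was 0.50 (camera adjusted p = 3.08e-07, adjusted p = 0.458 with an estimated correlation). Of pyrimidine synthesis genes, 1 of 13 measured members rose, 7 fell and 5 did not pass (2 rose and 10 fell adjusted over the list alone). Their median was -0.35, 0.06 with 1 member per run and no call (camera adjusted p = 4.25e-04, adjusted p = 0.458 with an estimated correlation). For type IV pili, 0 of 6 measured members rose, 3 fell and 3 did not pass (1 rose and 3 fell adjusted over the list alone). Their median was -0.32, -0.10 with 1 member per run (camera adjusted p = 0.00212, adjusted p = 0.280 with an estimated correlation). Its pullulanase genes SSA_0453 (-2.06) and pulA (-1.40) and pilus gene SSA_2317 (-0.54) fell. In the heat shock list at 30 against 20 min, 4 of 15 measured members rose, 0 fell and 11 did not pass (the same adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.00268, adjusted p = 0.280 with an estimated correlation). In amino acid synthesis, 0 of 63 measured members rose, 7 fell and 56 did not pass (the same adjusted over the list alone). Their median was -0.09, -0.03 with 1 member per run and no call (camera adjusted p = 0.0354, adjusted p = 0.724 with an estimated correlation). That call was lost without 20 min replicate 1 (0.0528) or 2 (0.0569) or 30 min replicate 2 (0.129). The cobalamin calls at 20 against 10 and 30 against 20 min held without any 1 library. In all, 384 genes differed, 127 higher and 257 lower at 30 min (edgeR), of which 2 rose and 74 fell by at least 2-fold. Without 1 library 1 to 4 rose and 56 to 80 fell so far. The split was 225 higher and 215 lower with library totals. Camera further called glycolysis and fermentation without 20 min replicate 1 (0.0414).

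Between 10 and 30 min the fructose genes showed the widest difference. fruB (-6.47), fruA (-5.97), fruR (-5.41) and SSA_1752 (-4.77) were lower at 30 min, fruB 88.8-fold (edgeR adjusted p = 1.32e-05), and SSA_0224 (2.70), SSA_2023 (2.67), SSA_0222 (2.60) and SSA_0157 (2.53) were higher. For ribosomal proteins, 0 of 52 measured members rose, 40 fell and 12 did not pass (0 rose and 46 fell adjusted over the list alone, 1 rose and 28 fell with library totals, median -0.42). Their median was -0.61 (camera adjusted p = 3.59e-10, adjusted p = 0.315 with an estimated correlation). In pyrimidine synthesis, 1 of 13 measured members rose, 7 fell and 5 did not pass (the same adjusted over the list alone). Their median was -0.47, -0.0041 with 1 member per run and no call (camera adjusted p = 1.87e-05, adjusted p = 0.315 with an estimated correlation). For transcription and translation factors between 10 and 30 min, 0 of 24 measured members rose, 13 fell and 11 did not pass (0 rose and 14 fell adjusted over the list alone, 2 rose and 7 fell with library totals, median -0.05). Their median was -0.24 (camera adjusted p = 0.00148, adjusted p = 0.458 with an estimated correlation). In oxidative stress and redox, 10 of 16 measured members rose, 2 fell and 4 did not pass (the same adjusted over the list alone). Their median was 0.57 (camera adjusted p = 0.00357, adjusted p = 0.544 with an estimated correlation). For DNA repair, 18 of 29 measured members rose, 0 fell and 11 did not pass (21 rose and 1 fell adjusted over the list alone). Their median was 0.27 (camera adjusted p = 0.00580, adjusted p = 0.578 with an estimated correlation). For the F-type ATPase list between 10 and 30 min, 13 of 14 measured members rose, 0 fell and 1 did not pass (14 rose and 0 fell adjusted over the list alone). Their median was 0.38 (camera adjusted p = 0.00773, adjusted p = 0.662 with an estimated correlation). Among glycolysis and fermentation genes, 12 of 24 measured members rose, 4 fell and 8 did not pass (12 rose and 5 fell adjusted over the list alone). Their median was 0.30, -0.09 with 1 member per run and no call (camera adjusted p = 0.0348, adjusted p = 0.486 with an estimated correlation). That call was lost without 10 min replicate 1 (0.0645), with library totals (0.0661) or thinned (0.0504). In all, 948 genes differed, 481 higher and 467 lower at 30 min (edgeR), of which 71 rose and 55 fell by at least 2-fold. The split was 914 higher and 264 lower with library totals. Camera further called amino acid synthesis without 10 min replicate 2 (0.04998), glycogen and amylase without 10 min replicate 1 (0.00290) and type IV pili without 10 min replicate 1 (0.0490), and with library totals other proteases and folding factors (0.0439). Apart from these, camera called no list left unnamed between durations. With 1 member per run it called 2, 4 and 4 lists from 10 to 20, 20 to 30 and 10 to 30 min. Ribosomal proteins and transcription and translation factors were in the first and last, DNA repair and oxidative stress in the last. Heat shock, PTS, glycogen and type IV pili with pullulanases were in the second. The direction for pyrimidine synthesis then turned upward in the last 2, uncalled.

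The responses at 20 and 30 min were closer to each other than either was to that at 10 min on every measure taken, a difference not itself tested. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.908 for 20 and 30 min, 0.766 for 10 and 20 min and 0.770 for 10 and 30 min. Unchanged groups simulated against the shared untreated libraries gave r = 0.497, 0.516 and 0.487 (mean of 20 simulations). The covariances were 0.757, 0.408 and 0.376, against simulated values of 0.0131, 0.0127 and 0.0127, differences of 0.744, 0.395 and 0.363. At 20 and 30 min 627 genes were higher and 629 lower in both, where independent lists of these sizes would share 247 and 238, and 11 changed in opposite directions. For 10 and 20 min the shared calls were 433 higher and 446 lower, against 182 and 179 for independent lists, with 21 opposite. For 10 and 30 min they were 444 and 456, against 183 and 184, with 35 opposite. The simulations shared 0 calls, and the 3 untreated libraries were too few to split, so part of the excess may come from the shared controls.

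The authors' deposited table lists 611 tested genes at a q-value under 0.05 for 10 min against untreated, 1114 for 20 min and 1066 for 30 min. Of those in the authors' deposited table, 556, 897 and 953 were also called by edgeR here. Between durations the authors' deposited table lists 828 for 10 and 20 min, 486 for 20 and 30 min and 650 for 10 and 30 min, of which 524, 220 and 526 were called here.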

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

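The tests of time in culture and of scaling, depth and gene length as the whole of a change, together with thinning and the use of predicted RNAs, were chosen after the results they concern were seen. Differences between durations were tested directly (edgeR, adjusted), with 983 genes between 10 and 20 min, 384 between 20 and 30 min and 948 between 10 and 30 min. Camera's called lists had median log2 differences between 10 and 20 min of -0.67 for ribosomal proteins, -0.26 for transcription and translation factors, 1.58 for PTS sugar uptake, 0.69 for glycolysis and fermentation, 0.18 for arginine deiminase system, 0.65 for cobalamin, propanediol and ethanolamine and 0.54 for glycogen and amylase. From 20 to 30 min heat shock had a median of 0.21, F-type ATPase 0.50, PTS sugar uptake -0.89, pyrimidine synthesis -0.35 and amino acid synthesis -0.089. Cobalamin, propanediol and ethanolamine had -0.60, glycogen and amylase -1.05 and type IV pili, where pullulanase genes fell most, -0.32. From 10 to 30 min ribosomal proteins had -0.61, transcription and translation factors -0.24, F-type ATPase 0.38 and glycolysis and fermentation 0.30. Pyrimidine synthesis had -0.47, DNA repair 0.27 and oxidative stress and redox 0.57. With an estimated correlation only glycogen and amylase between 20 and 30 min was called (adjusted p = 0.0330).

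The genes with the largest log2 differences between 10 and 20 min were SSA_0222 (4.18), SSA_2023 (4.17), SSA_0221 (4.12), SSA_0220 (4.11), fruB (-4.17), SSA_1752 (-4.04), dexS (-3.66) and fruR (-3.17). Between 20 and 30 min they were SSA_1112 (1.09), SSA_1052 (1.02), SSA_0288 (0.97), lacC (0.94), fruA (-3.01), fruB (-2.31), SSA_0379 (-2.28) and fruR (-2.24), with fruA at -2.35 without 20 min replicate 1 and fruB at -1.66 without 20 min replicate 1 and not called there (edgeR adjusted p = 0.0662), nor without 30 min replicate 2 or 30 min replicate 3 (0.0785 and 0.0649). Between 10 and 30 min they were SSA_0224 (2.70), SSA_2023 (2.67), SSA_0222 (2.60), SSA_0157 (2.53), fruB (-6.47), fruA (-5.97), fruR (-5.41) and SSA_1752 (-4.77). The fruB difference between 10 and 20 min was -4.82 without 20 min replicate 1. Predicted RNAs, which the comparisons leave out, also differed from untreated cells, 40 of 88 at 10 min, 56 at 20 min and 56 at 30 min (edgeR, adjusted).

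PTS sugar uptake genes rose at 20 min with a list median of 2.37 (1.07 to 2.88). The range resamples its 33 members, from 16 runs, as if independent. The median was 2.60 (1.30 to 3.11) with library totals alone and 2.35 (1.09 to 2.92) after thinning. Library totals shift all genes almost alike, here upward, so using TMM did not add to the rise. A shift that small could not end it, so scaling as the whole is not decided. Mean depth was alike (6.36e+06, untreated 6.19e+06) and thinning keeps expected changes, so it cannot decide. With 0 unheated groups sampled later, heat and time in culture both stay open.

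Ribosomal protein genes fell at 20 min with a list median of -1.27 (-1.38 to -1.22). With library totals alone it was -1.04 (-1.14 to -0.99), a shift nearly common to all genes. Part of the fall thus depends on scaling, but so small a shift cannot decide on the whole. Non-ribosomal genes matched on length and expression (median 411 against 367.5 bp, log2 CPM 9.82 against 10.61) had a median of -0.47 (-0.58 to -0.20). The ribosomal median lay -0.80 from it, which argues against length as the whole. The matched genes fell too, but with both matched, length and expression cannot be told apart. Time in culture stays open, as above.

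Between 20 and 30 min, 74 genes fell and 2 rose by at least 2-fold, SSA_1112 and SSA_1052 being those that rose. After thinning to equal gene totals 78 fell, so a difference in depth is argued against, and without any 1 library of the 20 min group at least 67 did, which argues against a single 20 min library. The count was 56 without 30 min replicate 2 and 65 with library totals alone, and 1 to 4 rose without 1 library. Of the 74 genes, 65 had been called higher and 4 lower than untreated at 20 min, and of those higher 43 were still called higher at 30 min, 13 were not called and 9 were lower. No biological explanation was tested, since time at 43 °C and time in culture rise together.

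The 6 libraries of each comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Regrouped in the 12-library fit, splits other than the real one called 0 genes each time (edgeR adjusted). These mix conditions, widening the spread, so their low counts decide nothing. At an unadjusted p under 0.05 the real split and the highest other gave 1246 and 338 at 10 min, 1537 and 122 at 20 min, 1556 and 238 at 30 min, 1153 and 152 between 10 and 20 min, 638 and 208 between 20 and 30 min and 1149 and 297 between 10 and 30 min.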

How the results depend on the processing

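Thinning to equal gene totals, keeping predicted RNAs and taking 1 list member per run of adjacent genes were chosen after the data were seen. Counts of changed genes stayed within 1.5 times the reported ones with DESeq2's size factors or test, library totals, either count filter, stable or predicted RNAs kept, thinning, the replicate block or only the groups compared. Over these they ran, in the order 10, 20 and 30 min, then 10 to 20, 20 to 30 and 10 to 30 min, as 919 to 1145, 1341 to 1513, 1399 to 1579, 860 to 1104, 329 to 449 and 840 to 1178. A 2-fold minimum, which removes smaller changes by construction, left 174, 407, 430, 171, 76 and 126, and 118, 323 and 128 shared calls for 10 and 20, 20 and 30, and 10 and 30 min, from 879, 1256 and 900. limma-voom with quality weights called 661 genes between 20 and 30 min, and the cause was not tested. Leaving out 1 library gave 898 to 1111, 1289 to 1404, 1341 to 1439, 668 to 932, 256 to 350 and 709 to 912 in the same order, and 8 to 10, 10 to 12 and 9 to 11 lists at 10, 20 and 30 min and 7 to 10, 7 to 8 and 7 to 8 between durations. The pseudocount alternative was for other units and was not run on counts. Depth was lowest at 30 min, and with all libraries thinned to the lowest gene total 980, 1341, 1419, 868, 349 and 878 genes were called.

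Replicate numbers did not pair the libraries by the rule used, which needed every same-number correlation to be over 0.1. Deviations of same-numbered libraries correlated at -0.47 to 0.48 in 18 pairs, 6 over 0.1. Of 12 libraries 0 matched their own number best in every other group. With a replicate block the counts were 1023, 1377, 1431, 860, 329 and 840, and 10, 10 and 11 lists were called at 10, 20 and 30 min and 7, 8 and 7 between durations, PTS at 30 min being gained (0.0345). Among named genes the block ended the calls of dltA at 10 min (0.0524) and ctsR at 30 min (0.0630), and it changed no other call of a named gene or list.

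Camera with an estimated correlation called 0, 0 and 0 lists at 10, 20 and 30 min (3, 5 and 5 at an unadjusted p under 0.05), against 10 at each with the preset one, 18, 20 and 22 by fry and 4, 4 and 4 with 1 member per run. From 10 to 20, 20 to 30 and 10 to 30 min the preset one called 7, 8 and 7, the estimated one 0, 1 and 0, fry 20, 12 and 17 and 1 member per run 2, 4 and 4. List names are shortened here. The adjusted p-values with an estimated correlation are given per comparison. At 10 min they were 0.0601 for heat shock, 0.217 for ribosomal and reductase, 0.372 for tRNA synthetases, 0.328 for translation factors and glycolysis, 0.673 for PTS, fatty acids and amino acids and 0.710 for cobalamin. At 20 min they were 0.209 for heat shock, 0.107 for ribosomal, 0.628 for tRNA synthetases, 0.217 for translation factors and glycolysis, 0.461 for PTS, 0.673 for fatty acids, 0.316 for arginine deiminase, 0.231 for reductase and 0.328 for glycogen. At 30 min they were 0.0816 for heat shock, 0.115 for ribosomal, 0.572 for tRNA synthetases and pyrimidines, 0.231 for translation factors, glycolysis and reductase, 0.673 for fatty acids and amino acids and 0.665 for oxidative stress. From 10 to 20 min they were 0.315 for ribosomal, glycolysis and glycogen, 0.458 for translation factors and PTS, 0.417 for arginine deiminase and 0.662 for cobalamin. From 20 to 30 min they were 0.280 for heat shock and type IV pili, 0.458 for F-type ATPase, pyrimidines and cobalamin, 0.315 for PTS and 0.724 for amino acids. From 10 to 30 min they were 0.315 for ribosomal and pyrimidines, 0.458 for translation factors, 0.662 for F-type ATPase, 0.486 for glycolysis, 0.578 for DNA repair and 0.544 for oxidative stress. Adjusted p-values of calls lost with 1 member per run, where fewer genes are tested, are these. At 10 min they were 0.127 for PTS, 0.333 for glycolysis, 0.728 for fatty acids, 0.595 for amino acids, 0.835 for cobalamin and 0.172 for reductase. At 20 min they were 0.235 for heat shock, 0.412 for glycolysis, 0.930 for fatty acids, 0.554 for arginine deiminase, 0.239 for reductase and 0.144 for glycogen. At 30 min they were 0.458 for glycolysis, 0.890 for pyrimidines, 0.930 for fatty acids, 0.131 for oxidative stress, 0.172 for amino acids and 0.235 for reductase. From 10 to 20 min they were 0.189 for PTS, 0.758 for glycolysis, 0.802 for arginine deiminase and cobalamin and 0.130 for glycogen. From 20 to 30 min they were 0.223 for F-type ATPase, 0.782 for amino acids and 0.130 for cobalamin. From 10 to 30 min they were 0.512 for F-type ATPase and 0.802 for glycolysis. Camera's direction for pyrimidines then reversed to up, uncalled, from 20 to 30 min (0.735, median 0.064) and from 10 to 30 min (0.817, median -0.0041).

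fry tests whether members move one way and compares with no other genes, so it called more lists. The calls it gained at 10 min had adjusted p-values of 0.0307 for purines, 0.00139 for peptidoglycan, 0.0385 for cell envelope, 7.48e-04 for arginine deiminase, 0.00149 for adhesins, 0.00693 for metal uptake, 0.0141 for glycogen, 0.00198 for cell division and 0.0123 for transposases. At 20 min they were 0.00828 for pyrimidines, 0.00109 for competence, 0.00139 for DNA repair, 1.70e-04 for peptidoglycan, 0.00115 for cell envelope, 4.99e-04 for oxidative stress, 0.0124 for amino acids, 0.0318 for type IV pili, 7.97e-04 for cell division and 6.73e-04 for transposases. At 30 min they were 7.97e-04 for other proteases and transposases, 0.0237 for F-type ATPase, 0.00790 for PTS, 0.00650 for competence, 4.35e-04 for DNA repair, 7.17e-04 for peptidoglycan, 0.00271 for cell envelope, 6.89e-06 for arginine deiminase, 7.26e-04 for type IV pili, 0.0402 for cobalamin and 0.00466 for cell division. From 10 to 20 min they were 0.00597 for heat shock, 0.0215 for other proteases, 0.0101 for purines, 0.00467 for pyrimidines, 0.00749 for competence, 0.00187 for DNA repair, 0.0487 for peptidoglycan, 0.0360 for cell envelope, 0.00415 for oxidative stress, 0.0145 for adhesins, 9.87e-04 for metal uptake, 0.0224 for reductase and 0.0310 for transposases. From 20 to 30 min they were 0.0110 for other proteases and glycolysis, 0.00848 for arginine deiminase and 0.0467 for metal uptake. From 10 to 30 min they were 0.00241 for heat shock, 5.57e-04 for other proteases, 0.0391 for competence, 5.70e-04 for arginine deiminase, 4.38e-04 for type IV pili, 0.0452 for adhesins, 0.0202 for metal uptake, 0.00976 for reductase, 0.00725 for glycogen and 0.0360 for transposases. It lost cobalamin at 10 min (0.0509). Type IV pili at 20 min had fry's direction up with a median of -0.21, 0.02 with library totals alone, and arginine deiminase from 20 to 30 min down with a median of 0.026. Library totals alone gained 0.0446 for adhesins at 10 min, 0.0446 for DNA repair, 0.0381 for arginine deiminase and 0.0216 for cobalamin at 30 min, 0.0324 for DNA repair and 0.0395 for oxidative stress from 10 to 20 min and 0.0439 for other proteases from 10 to 30 min (camera adjusted p). Glycolysis from 10 to 30 min was lost with them (0.0661) and by thinning (0.0504). Leaving out 1 library moved camera's adjusted p over 0.0274 to 0.202 for amino acids at 20 min, 0.04998 to 0.402 for amino acids from 10 to 30 min, 0.00956 to 0.129 for amino acids from 20 to 30 min, 0.00101 to 0.0724 for cobalamin at 10 min, 0.0238 to 0.277 for cobalamin at 30 min, 0.00620 to 0.0806 for fatty acids at 10 min, 0.0109 to 0.0778 for fatty acids at 30 min, 0.04998 to 0.314 for fatty acids from 10 to 20 min, 0.00290 to 0.257 for glycogen from 10 to 30 min, 0.0207 to 0.0645 for glycolysis from 10 to 30 min, 0.0414 to 0.192 for glycolysis from 20 to 30 min, 0.0393 to 0.115 for oxidative stress at 20 min, 0.0192 to 0.129 for oxidative stress from 10 to 20 min, 0.0285 to 0.0710 for PTS at 30 min, 0.0371 to 0.174 for pyrimidines from 10 to 20 min, 0.0372 to 0.288 for adhesins at 10 min and 0.0490 to 0.205 for type IV pili from 10 to 30 min. With library totals alone the log2 fold changes at 30 min of SSA_0009, 0.20 against -0.08, and htpX, 0.040 against -0.24, reversed, as a shift of all genes brings by construction. Apart from what construction shows, the cause was not tested. Over all alternatives, 3899 of 3944 values for 232 named gene results kept direction and call, 35 lost the call, 8 gained it and 2 reversed. For 156 list results, 1693 of 1872 values kept both, 93 lost the call, 84 gained it and 2 reversed.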

Other observations

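These genes and tests were chosen after their values were seen. Among the 43 genes called in opposite directions at different durations was a run of neighbours in arginine synthesis. At 10, 20 and 30 min argC had log2 fold changes against untreated of 0.76, -0.53 and -1.37, argJ of 0.67, -0.26 and -1.24, argB of 0.72, -0.11 and -1.15 and SSA_0760, an acetylornithine aminotransferase gene, of 0.73, -0.08 and -1.21. The fructose genes fruR, fruB and fruA had 1.51, -1.66 and -3.90, 1.82, -2.34 and -4.65 and 1.61, -1.35 and -4.36, called as higher at 10 min and lower at 30 min, with fruB at -2.96 without 20 min replicate 1 at 20 min.

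Predicted RNAs are short features the authors' table lists beside the genes, and those given here had large changes. predictedRNA_9 (216485 to 216509, plus strand), between SSA_0220 and SSA_0221, had a log2 fold change of 6.69 at 20 min, and predictedRNA_10 (218201 to 218272), between SSA_0222 and SSA_0224, 6.51 at 20 min and 5.11 at 30 min. predictedRNA_78 (2007365 to 2007378, minus strand), beside dnaK, had 1.67 at 10 min. predictedRNA_20 (512371 to 512643, minus strand), between SSA_0513 and SSA_0514, stood at -1.09, -1.72 and -1.91 at 10, 20 and 30 min, where SSA_0514 stood at -1.05, 0.71 and -1.22. Of 88 predicted RNAs, 22 were higher and 18 lower at 10 min, and 25 and 31 at both 20 and 30 min (edgeR adjusted).

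The genes SSA_0219 to SSA_0224 end 203 bp before groES on the same strand, so transcripts running on from SSA_0224 could add to groES counts. Between 10 and 20 min SSA_0224 rose by 4.10 on the log2 scale while groES differed by -0.010 (SE 0.12, edgeR adjusted p = 0.955). groEL, next on that strand, differed by -0.18 (SE 0.06), so groES was higher against it by 0.17, with an upper limit of 0.43 at 2 SE. Read-through into groES and none cannot be told apart from these values, since the change of groES without it is not known.

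Within groups, 1 component carried 44.0% of the variance of log2 CPM about the group means. Its score was positive in 1 library of each group, untreated replicate 1 (9.17), 10 min replicate 2 (6.29), 20 min replicate 3 (4.05) and 30 min replicate 2 (7.37), and negative in the other 8. No label describes a technical difference between these libraries.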
